A study of Mus musculus with 8 samples.

How the data were processed

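Poly(A) RNA from the gastrocnemius muscle of C57BL/6 mice aged 9 weeks was sequenced after library preparation with a stranded TruSeq mRNA kit, per the labels' protocols. Controls carried a floxed androgen receptor gene. In the knockout mice the HSA-Cre driver, which acts in skeletal myofibres, removed the receptor from the fibres, per the labels and the series' design text. Each group held 4 samples with separate labels. The labels do not say in so many words that each sample was a separate mouse, so p-values measure the spread between these samples.

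The authors' deposited table holds 48709 Ensembl gene identifiers, with raw read counts for 8 libraries. The 8 columns are named WT_158 to WT_161 for the controls and ARKO_170, ARKO_163, ARKO_164 and ARKO_165 for the knockouts. The numbers in these names match no sample title, so each column was used as a replicate of its group with no pairing, and the libraries are called by their column names. Per the submitters' processing notes and the design text, bcl2fastq 2.17.1.14 was used, reads were assigned to the mm10 genome build and counted with HOMER, and edgeR and DESeq were run. The aligner, the gene annotation release and the strand setting of the counting were not given in the sources used here. A further 16 per-sample columns hold normalized values and were not used.

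The same deposited table holds the authors' own comparison. Per the file headers it gives a mean normalized signal for each gene (baseMean), a log2 fold change with its standard error, a test score (stat) and p-values with adjusted p-values. The layout is that of DESeq2 results. The score equalled the log2 fold change divided by its standard error, and the mean signal equalled that of a DESeq2 run made here to within 4.88e-13%. In all 497 genes called in that table the sign of the authors' log2 fold change matched knockout minus control in the counts.

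Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults, which left 14606 genes, and libraries were scaled by TMM factors. The quasi-likelihood test (glmQLFit and glmQLFTest, robust) compared the groups with no covariate, two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Expression is given as CPM (edgeR's read counts scaled to a common library size, here with TMM factors), as mean ± SD. Log2 fold changes are knockout minus control. Standard errors were taken as the unshrunken log2 fold change divided by the square root of the F statistic, and 95% confidence intervals follow from them. The Ar level was also tested by an exact two-sided permutation test of log2 CPM over all 70 assignments of the 8 libraries, whose smallest possible p is 0.0286.

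Before the data were examined, 35 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The 34 lists with at least 5 tested genes were tested by camera in limma 3.58.1 on voom values with the preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The lists come from textbook knowledge of muscle and androgen action and include markers of other cell types in muscle. Named genes are Ar, the 12 largest increases and 12 largest decreases among genes past the threshold, up to 4 members of each list past the threshold, the 4 adult myosin heavy chains and the sex-linked genes. The increases and decreases also needed a mean of at least 1 CPM in the higher group and no overlap between the groups. For a list with no member past the threshold, the 2 members with the smallest p were taken and are given as values.

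Gene coordinates are from GENCODE M21, whose GRCm38 build is that of mm10, matched by Ensembl identifier for 14581 of the 14606 tested genes. Libraries were compared in pairs within each group only, and every such pair differed by more than counting noise. The chi-square per degree of freedom was 14.2 or more over genes with at least 20 reads in the pair. No column was therefore a copy or a resequencing of another library of its group. This covers counting error only and does not tell separate mice from repeat preparations of the same RNA. The 8 libraries were treated as separate replicates because the labels list 8 samples.

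The library totals ran from 35887034 to 63115913 counts. The common biological coefficient of variation was 14.7%. The tests were checked on simulated data made from the real means, spreads and library sizes, with 200 changed genes in each of 3 runs. In this comparison edgeR, on 14413 genes, recovered 50.2% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 94.9% of those changed 4-fold, and 6.37% of its calls were false. DESeq2 1.42.0, on 14606 genes, recovered 60.2%, 83.6% and 97.5% with 15.3% false calls, and limma-voom recovered 48.8%, 78.1% and 95.5% with 5.23% false calls. A simulated list of 20 further genes, changed 1.3-fold and counted as truly changed, was added in each run. It had an unadjusted p under 0.05 in 3 of 3 runs by camera with either correlation and by fry. The simulated genes were drawn independently, and no simulated library was set apart from its group. The recovery and false-call rates may therefore not hold for libraries that differ within a group. For DESeq2 the rates cover filtered genes only, not the run on 27668 genes. Nor does this check show the power for lists whose genes vary together, or after adjustment over the lists. The test of neighbouring genes gave p under 0.05 in 0 of 40 random sets of 99 genes and in 40 of 40 sets with 8 planted pairs. These sets were drawn without regard to expression. The planted pairs outnumber the 5 found within 100 kb among genes that fell, so the power for 5 pairs is not shown.

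The alternatives were DESeq2 size factors, library size alone and upper-quartile factors in place of TMM, DESeq2 and limma-voom in place of edgeR, no filter or a filter of 1 CPM in 4 libraries, a 2-fold minimum, and each library left out in turn. DESeq2 was run on the counts without filterByExpr and tested 27668 genes, so this alternative changed the tool and the filter together. Alternatives chosen after the data had been seen were sample quality weights in limma-voom, fits without the ribosomal RNA-like transcripts Gm42418 and AY036118, with TMM or library size alone, and a fit without WT_159 and ARKO_163. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.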

Results

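The series compared gastrocnemius muscle, a calf muscle made mostly of fast fibres, between mice that lack the androgen receptor in their myofibres and controls that carry only the floxed gene. The question was which transcripts of the muscle differ when the fibres lack the receptor. Messenger RNA was sequenced from 4 control and 4 knockout samples at 9 weeks of age. The control libraries held 36680510 (WT_158), 43403388 (WT_159), 41687630 (WT_160) and 44987629 (WT_161) counts in total. The knockout libraries held 36266634 (ARKO_170), 63115913 (ARKO_163), 35887034 (ARKO_164) and 55774062 (ARKO_165) counts. The fast myosin gene Myh4 took the largest share of counts in 7 libraries, between 4.34% and 6.64%. In ARKO_163 the ribosomal RNA-like transcript Gm42418 came first with 6.26%. On the first principal component of log2 CPM, which held 39.1% of the variance, the knockout libraries lay between 2.10 and 22.01 and the controls WT_158, WT_160 and WT_161 between -23.2 and -13.2. The control WT_159 lay at 4.55, within the range of the knockout libraries.

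Ar, the targeted gene (ENSMUSG00000046532, chromosome X, 98148769 to 98323215, mm10), fell 12.0-fold in knockout muscle. Its level was 44.3 ± 5.82 CPM (SD, n = 4) in control and 3.67 ± 0.855 CPM (SD, n = 4) in knockout muscle, which is 8.28% of the control mean. The control libraries held 38.7 CPM (WT_158), 51.0 CPM (WT_159), 40.2 CPM (WT_160) and 47.2 CPM (WT_161) of Ar. The knockout libraries held 4.38 CPM (ARKO_170), 4.07 CPM (ARKO_163), 2.44 CPM (ARKO_164) and 3.77 CPM (ARKO_165), from 88 to 239 counts each. The log2 fold change was -3.59 (SE 0.16, 95% confidence interval -3.95 to -3.23), with an adjusted p of 2.57e-06 in edgeR's quasi-likelihood test. An exact two-sided permutation test over the 70 assignments gave p = 0.0286, the smallest it can give. Gene-level counts take reads from every part of the transcript, so they do not separate transcripts of other cell types from transcripts that lack the deleted part.

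Among 14606 tested genes 156 changed in knockout muscle, of which 57 rose and 99 fell. Slc30a2, a zinc transporter, fell 14.2-fold from 25.4 ± 12.1 to 1.81 ± 0.710 CPM (SD, n = 4 each). Mss51, a mitochondrial protein of skeletal muscle, fell 7.06-fold from 116 ± 47.0 to 16.5 ± 5.08 CPM. Slc2a3, the glucose transporter GLUT3, fell 6.08-fold from 11.7 ± 4.08 to 1.91 ± 0.981 CPM. Amd1, the decarboxylase that feeds the synthesis of spermidine and spermine, fell 4.02-fold from 569.7 ± 235 to 142 ± 27.6 CPM. Spns2, an exporter of sphingosine-1-phosphate, fell 3.89-fold from 97.6 ± 29.7 to 25.1 ± 5.00 CPM. Tfcp2l1, a transcription factor, fell 4.98-fold from 20.996 ± 7.37 to 4.20 ± 1.42 CPM. The adjusted p of these genes ran from 0.0179 for Spns2 to 0.0427 for Slc2a3 in edgeR's quasi-likelihood test. With each of the 8 libraries left out in turn, Slc30a2, Mss51 and Slc2a3 kept their call in 1 fit, that without WT_159. Amd1 and Tfcp2l1 kept it in 2 fits and Spns2 in 5.

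**Figure D1:**
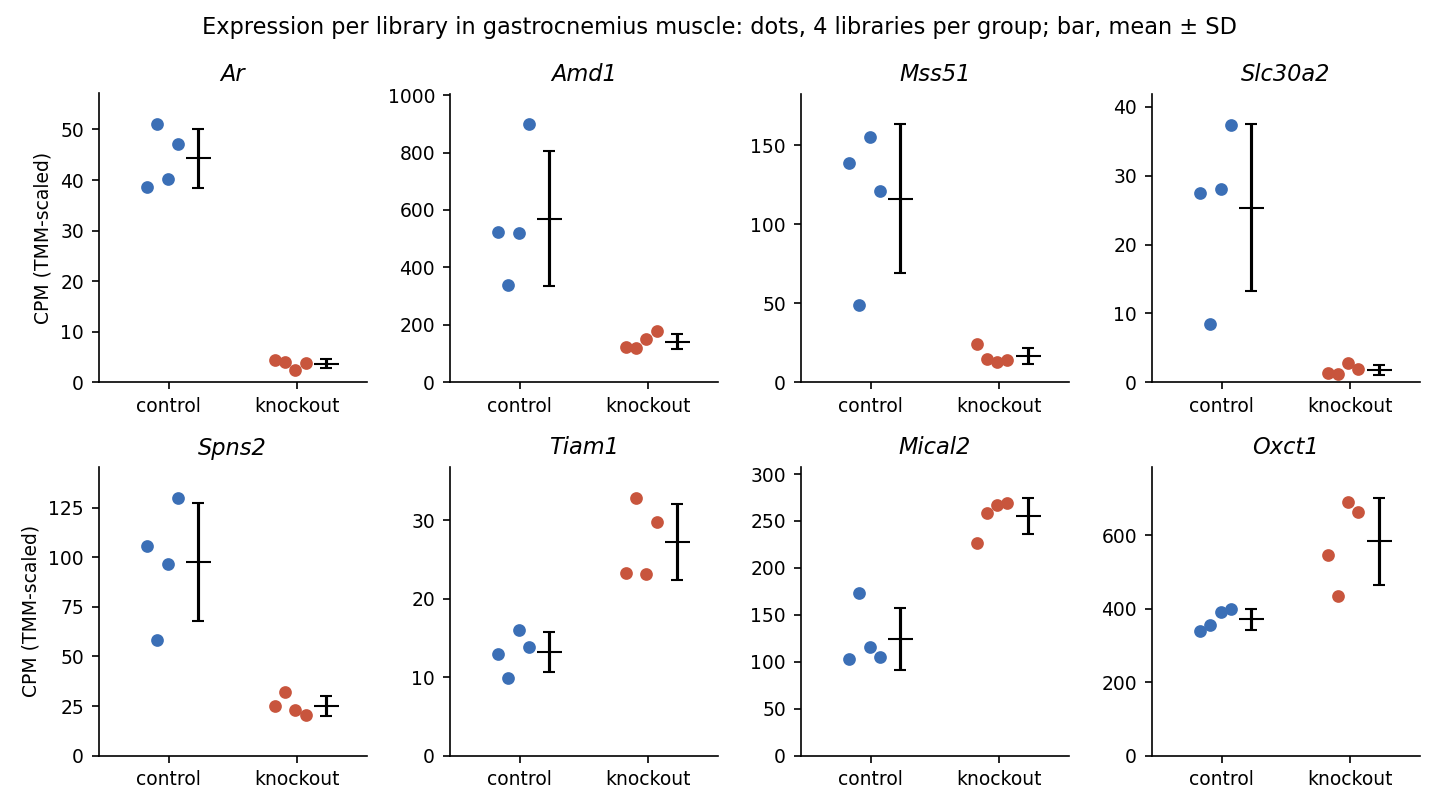
Expression per library of Ar, 4 genes that fell (Amd1, Mss51, Slc30a2, Spns2) and 3 genes that rose (Tiam1, Mical2, Oxct1), in CPM on linear axes from 0, with dots for the 4 control and 4 knockout libraries and bars for the mean and SD. In each panel the 4 knockout dots lie apart from the 4 control dots, as in all 156 changed genes, from which these were picked. Ar lies at 2.44 to 4.38 CPM in knockout against 38.7 to 51.0 CPM in control libraries.

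The other named decreases were at lower levels. Fscn2, an actin-bundling fascin known from the retina, fell 18.9-fold from 1.25 ± 0.383 to 0.0643 ± 0.0258 CPM (SD, n = 4 each). Otog, which encodes otogelin of the inner ear, fell by 2.76 on the log2 scale, and Cd27, a receptor of the TNF receptor family, fell by 2.48. Tph1, the enzyme that starts serotonin synthesis, fell by 2.167. Amd2 fell by 2.08, but it is a near copy of Amd1 and held between 0.745% and 1.81% of the counts of Amd1 in each library, so its value is uncertain because reads of Amd1 could be counted there. The adjusted p of these genes ran from 0.00103 for Fscn2 to 0.0455 for Tph1 in edgeR's quasi-likelihood test. All 4 knockout libraries lay below all 4 controls for each, which the rule for naming these genes required.

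Mical2, an oxidase of actin filaments, rose 2.05-fold from 124 ± 33.3 to 255 ± 19.4 CPM (SD, n = 4 each). Tiam1, an activator of the GTPase Rac1, rose 2.08-fold from 13.2 ± 2.54 to 27.2 ± 4.84 CPM. Rab15, a small GTPase of membrane traffic, rose 2.03-fold from 3.98 ± 0.700 to 8.11 ± 1.01 CPM. The remaining named increases had means of at most 4.14 CPM. They were Dmp1 (dentin matrix protein) at 4.26-fold, Maats1 (a protein of cilia and flagella) at 3.24-fold, Hsbp1l1 at 2.84-fold, the calcium channel subunit gene Cacnb4 at 2.62-fold, the potassium channel gene Kcnu1 at 2.22-fold and Fam46c at 1.91-fold. The predicted genes Gm10851, Gm45531 and 5730419F03Rik rose 2.35-fold, 2.31-fold and 2.08-fold. Gm10851, Cacnb4, Rab15, Cd27 and Spns2 overlap a tested gene on the opposite strand (Pfkfb3, A430018G15Rik, Fntb, Vamp1 and Mybbp1a). The partners had log2 fold changes of -0.52, -0.53, -0.09, -0.06 and -0.20, none past the threshold. Because the strand setting of the counting is not known, reads of the partner counted in these genes are not excluded.

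**Figure D2:**
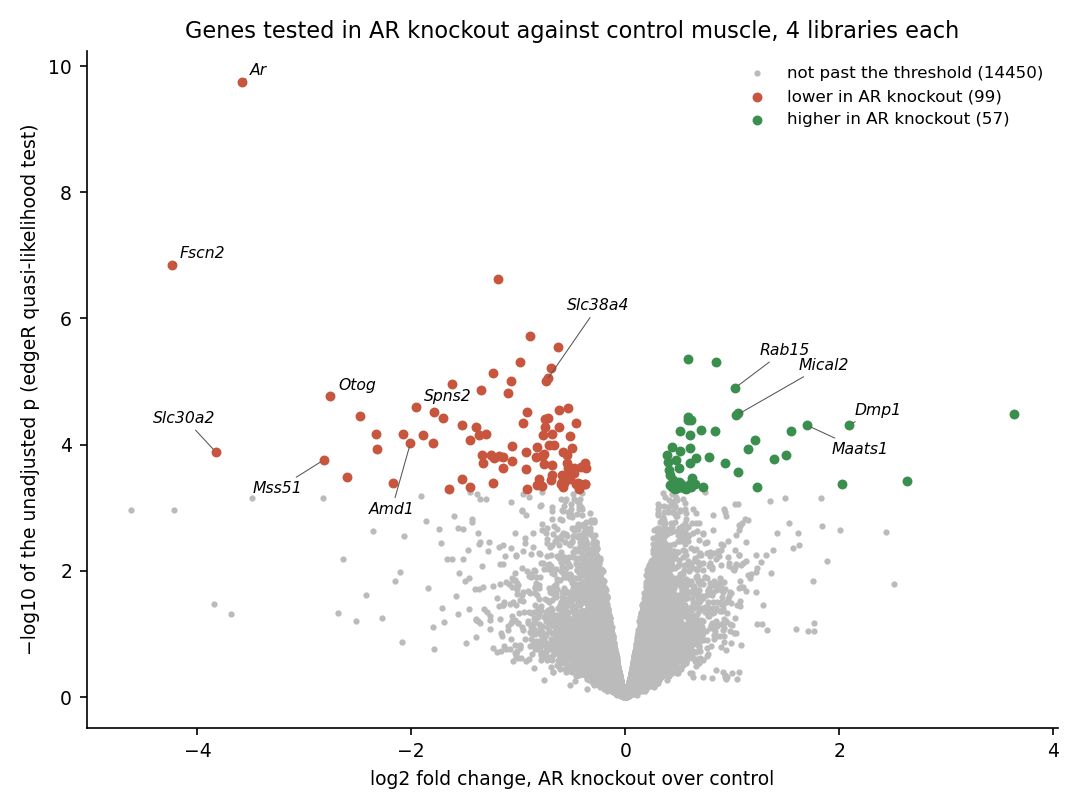
Each dot is 1 of 14606 tested genes, with the log2 fold change (AR knockout over control) on the horizontal axis and minus the log10 of the unadjusted p on the vertical axis. The 99 genes that fell and the 57 that rose are coloured, and Ar stands highest, at a log2 fold change of -3.59.

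Among the 156 changed genes 56 changed at least 2-fold, 41 of them downward, and 143 are annotated as protein coding. All 156 had no overlap between the groups, as had 7.26% of the tested genes, where chance gives 2.86%. Unadjusted, 2052 genes had a p under 0.05. A fit with 1 library fewer has less power, so lost calls do not by themselves show dependence on the library left out. The count changed with each library left out. It was 22 without WT_158, 550 without WT_159, 41 without WT_160, 61 without WT_161, 39 without ARKO_170, 45 without ARKO_163, 91 without ARKO_164 and 16 without ARKO_165. Without WT_159 all 156 genes were called again. Of the 34 named genes past the threshold 34 kept their sign in each of these 8 fits. Their groups did not overlap, so leaving out 1 library could hardly turn a sign, and the kept signs add no support. Of the 34, Ar, Fscn2 and Rab15 alone stayed past the threshold in all 8 fits. The other 31 lost the call in at least 1 fit, with adjusted p up to 0.163. Some, such as Slc30a2, Mss51, Slc2a3 and Cacnb4, kept it only without WT_159. DESeq2, run on 27668 genes without filterByExpr, called 501 genes, and edgeR with no filter on low counts called 301.

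Of 10 genes known to respond to androgens in muscle 3 fell, 0 rose and 7 were not past the threshold. The 3 were Amd1, Amd2 and Slc38a4, an amino acid transporter that fell 1.67-fold from 183 ± 26.8 to 109.6 ± 5.94 CPM (SD, n = 4 each, adjusted p = 0.0111). There 6 fell and 1 rose when adjusted over the list alone. Camera with the preset correlation gave an adjusted p of 7.16e-06, and the adjusted p was 0.472 with an estimated correlation. The mean of the list stood at -0.42 in WT_159 on the log2 scale relative to the control mean, between the other controls (0.00 to 0.37) and the knockout libraries (-1.21 to -0.61). In polyamine metabolism 2 of 21 tested genes fell and 0 rose, and both were the decarboxylase genes Amd1 and Amd2. Reads of Amd1 could be counted in Amd2, so in both lists these 2 calls may reflect 1 change. In that pathway 3 fell and 1 rose adjusted over the list alone. As a set the polyamine list was not past the threshold by camera (adjusted p = 0.0961). By fry for change in either direction its adjusted p was 0.00615. DESeq2 called 4 androgen-responsive genes lower and 1 higher, and 3 polyamine genes lower. By limma-voom 3 androgen-responsive and 2 polyamine genes were called, all lower. Amd1 was no longer called without WT_158, WT_160, ARKO_170, ARKO_163, ARKO_164 or ARKO_165, with adjusted p up to 0.0939 and log2 fold changes from -2.19 to -1.70 over all 8 fits. With WT_159 left out 4 androgen-responsive and 3 polyamine genes fell, Odc1 added to both lists. Without ARKO_165 neither list held a call, without WT_158, WT_160 or ARKO_163 Slc38a4 was the 1 call of the androgen-responsive list and the polyamine list held 0, and without ARKO_164 Igf1 was called higher.

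In branched-chain amino acid catabolism 2 of 28 tested genes rose and 0 fell. Oxct1, the enzyme that activates ketone bodies for oxidation, rose 1.57-fold from 371 ± 28.6 to 583 ± 118 CPM (SD, n = 4 each), and Acadsb, a short branched-chain acyl-CoA dehydrogenase, rose 1.37-fold from 89.7 ± 10.7 to 123 ± 6.55 CPM. Both had an adjusted p of 0.0455. Acadsb overlaps the annotation of Fgfr2 and Oxct1 that of BC037032, each on the opposite strand, with log2 fold changes of -0.78 and 0.51 for these partners, neither past the threshold. Adjusted over the list alone, 5 rose and 0 fell. DESeq2 called 4 genes of the list higher and limma-voom 1. The list's median log2 fold change was 0.18, with a camera adjusted p of 4.68e-06, and the adjusted p was 0.699 with an estimated correlation. The groups overlapped in the list's mean, with WT_160 (0.14) above ARKO_163 (0.06). In fatty acid uptake and oxidation 1 of 38 tested genes rose, in the whole test and adjusted over the list alone. It was Lpl, the lipase that frees fatty acids from circulating lipoproteins, which rose 1.43-fold from 459 ± 56.4 to 656 ± 66.4 CPM (adjusted p = 0.0455). DESeq2 called 1 fatty acid gene higher and limma-voom called 0, so Lpl was not called by limma-voom. This list had a median of 0.17, a camera adjusted p of 0.000572 and an adjusted p of 0.699 with an estimated correlation. Its mean in the control WT_159 (0.22) was above that in ARKO_163 (0.13) and ARKO_165 (0.05) and level with ARKO_164 (0.22). Acadsb and Lpl kept their calls in 1 of the 8 fits that left out a library, the fit without WT_159, and Oxct1 in 2, those without WT_159 and without ARKO_163. In the fatty acid list 4 genes were called higher without WT_159 (Cd36, Decr1, Lpl and Pdk4), and with any other library left out 0. The highest adjusted p, without WT_158, was 0.161 for Lpl and Oxct1 and 0.151 for Acadsb.

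The central energy pathways held no gene past the threshold. In the TCA cycle 0 of 23 genes changed, and the list had a median log2 fold change of 0.11 with a camera adjusted p of 0.0364, which became an adjusted p of 0.901 with an estimated correlation. Its mean in ARKO_163 (-0.07) was below all 4 controls. Its genes with the smallest p were Suclg2 (log2 fold change 0.28, adjusted p = 0.178) and Pcx (-0.64, adjusted p = 0.218). Glycolysis and glycogen had 0 of 32 genes past the threshold (camera adjusted p = 0.593), with Hk2 at -0.37 (adjusted p = 0.232) and Ppp1r3c at -0.35 (adjusted p = 0.312). Oxidative phosphorylation had 0 of 72 (camera adjusted p = 0.984), with Ndufab1 at 0.20 (adjusted p = 0.279) and Ndufs4 at -0.23 (adjusted p = 0.329). Adjusted over each list alone, these 3 lists held 0 changed genes as well. For glycolysis the median was 0.00 and the mean -0.02 with a downward test, and for oxidative phosphorylation the median was 0.00 and the mean -0.01 with an upward test. In edgeR 4 TCA cycle genes, 3 of glycolysis and 2 of oxidative phosphorylation had an unadjusted p under 0.05. DESeq2 called 1 TCA cycle gene lower and 0 in the others, and limma-voom called 0 in all 3 lists.

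The adult myosin heavy chains, which set the fibre type, were not past the threshold. Myh4, of the fastest fibres, had a log2 fold change of -0.15 (95% confidence interval -0.46 to 0.16). It was -0.10 (-0.33 to 0.14) for Myh1, -0.01 (-0.32 to 0.31) for Myh2 and -0.07 (-1.71 to 1.56) for Myh7, the slow isoform, whose interval is wide. The list of fast-fibre contractile genes had 0 of 18 members past the threshold (camera adjusted p = 0.266), and so had the slow-fibre list (0 of 18, camera adjusted p = 0.288). The members with the smallest p were Mylk4 (log2 fold change -1.08, adjusted p = 0.309), Myoz1 (-0.23, adjusted p = 0.362), Casq2 (0.52, adjusted p = 0.385) and Myoz2 (0.19, adjusted p = 0.519). Calcium handling and excitation-contraction coupling had 0 of 26 (camera adjusted p = 0.340), with Cacng1 at -0.36 (adjusted p = 0.191) and Camk2b at -0.20 (adjusted p = 0.300). At an unadjusted p under 0.05 edgeR had 1 fast-fibre, 0 slow-fibre and 3 calcium handling genes. DESeq2 and limma-voom called 0 in these lists, and 0 changed adjusted over each list alone.

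Musk, the receptor kinase that organises the neuromuscular junction, fell 2.53-fold from 12.8 ± 3.89 to 5.07 ± 0.917 CPM (SD, n = 4 each, adjusted p = 0.0277), and it was the 1 of 18 denervation-response genes past the threshold. Of these 18 genes 7 rose and 1 fell adjusted over the list alone. DESeq2 called 4 of them higher and 1 lower, and limma-voom 1 higher and 1 lower. The list had a median log2 fold change of 0.26, a camera adjusted p of 0.00394 and an adjusted p of 0.472 with an estimated correlation. The list's mean was 0.18 in the control WT_159 and 0.16 in ARKO_165, so the groups overlapped. Markers of Schwann cells and nerve, with a median of -0.52, also overlapped between the groups. Among ubiquitin-proteasome and autophagy atrogenes 1 of 32 rose and 1 fell. Ctsl, a lysosomal protease, rose 1.42-fold from 107 ± 7.75 to 153 ± 12.4 CPM (adjusted p = 0.0196), while Eif4ebp1, an inhibitor of translation, fell 1.72-fold from 33.8 ± 7.21 to 19.7 ± 2.04 CPM (adjusted p = 0.0278). Adjusted over that list alone, 4 rose and 2 fell. DESeq2 called 4 of its genes higher and 2 lower, and limma-voom 2 higher and 1 lower. The list was not past the threshold by camera (adjusted p = 0.459). By fry for change in either direction its adjusted p was 0.00615. In growth-factor and myostatin signalling 1 of 29 genes fell, the TGF-beta signal transducer Smad3, by 0.44 on the log2 scale (adjusted p = 0.0455). Adjusted over the list alone, 2 were lower and 1 higher (camera adjusted p = 0.340). By fry for change in either direction the growth-factor list had an adjusted p of 0.0171. In it DESeq2 called 1 gene higher and 2 lower, and limma-voom called 0, so Smad3 was not called there. With WT_159 left out 3 denervation-response genes were called higher (Cdkn1a, Chrna1 and Gadd45a) beside the fall of Musk, and with any other library left out 0 were called. The atrogenes had 4 higher (Cdkn1a, Ctsl, Foxo3 and Pdk4) and 2 lower (Eif4ebp1 and Fbxo32) without WT_159, and at most 1 call without any other library. Igf1 was called higher beside the fall of Smad3 without ARKO_164. Musk kept its call in 1 of 8 fits with a library left out (without WT_159), Smad3 and Eif4ebp1 in 2 and Ctsl in 3. The highest adjusted p was 0.108 for Musk (without ARKO_165), 0.141 for Smad3 (without WT_161), and 0.0979 for Eif4ebp1 and 0.0815 for Ctsl (both without WT_158).

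The cadherin gene Cdh15, on both the list of embryonic and regeneration markers and that of satellite cells, the stem cells of muscle, fell 1.297-fold from 24.3 ± 1.79 to 18.7 ± 0.730 CPM (SD, n = 4 each, adjusted p = 0.0455), and kept its call in 1 of 8 fits with a library left out (without WT_159), with an adjusted p of 0.134 without WT_158. It was the 1 of 14 and the 1 of 12 members past the threshold. With WT_159 left out Actc1 was called higher and Myf6 lower beside Cdh15 among the embryonic and regeneration markers, and with any other library left out neither list held a call. Adjusted over the list alone, 2 embryonic and regeneration markers rose and 1 fell, and of the satellite cell markers 1 fell. Neither list was past the threshold by camera (adjusted p = 0.722 and 0.898). By fry for change in either direction each had an adjusted p of 0.0159. DESeq2 called 2 embryonic and regeneration markers higher and 2 lower, and 2 satellite cell markers lower. In both lists limma-voom called 0, so Cdh15 was not called there. The embryonic list had a median of -0.14 and a mean of 0.18 with a downward test, and the satellite list a median of 0.08 and a mean of 0.03 with a downward test. Cell cycle genes had 0 of 20 members past the threshold, with a median log2 fold change of 0.42. Their camera adjusted p was 0.0187, and the adjusted p was 0.699 with an estimated correlation. The list's mean was 0.85 in ARKO_170 and 0.63 in ARKO_163, while ARKO_164 (0.17) and ARKO_165 (-0.04) lay within the control range (-0.30 to 0.21). Mki67 stood at 0.99 (adjusted p = 0.305) and Rrm2 at 0.69 (adjusted p = 0.301). For cell cycle genes edgeR had 4 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, as did the test adjusted over the list alone.

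The clock repressor Nr1d1 fell 1.68-fold from 178 ± 32.6 to 106 ± 9.57 CPM (SD, n = 4 each, adjusted p = 0.0185), the 1 of 19 circadian genes past the threshold, and its annotation overlaps that of Thra (log2 fold change -0.22, not past the threshold) on the opposite strand. Nr1d1 was no longer called without ARKO_165 (adjusted p = 0.0743) or without ARKO_170. Adjusted over the list alone, 3 circadian genes fell and 0 rose. DESeq2 called 2 circadian genes lower and limma-voom 1. The list's median was -0.13, with a camera adjusted p of 0.0303 and an adjusted p of 0.490 with an estimated correlation. Glucocorticoid-responsive genes had 0 of 22 past the threshold (camera adjusted p = 0.554), with Klf15 at a log2 fold change of 0.52 (adjusted p = 0.108) and Fbxo32, which encodes the ubiquitin ligase atrogin-1, at -0.72 (adjusted p = 0.178). Immediate early genes had 0 of 19 (camera adjusted p = 0.816), with Cyr61 at 0.50 (adjusted p = 0.108) and Arc at 0.44 (adjusted p = 0.428). In edgeR 3 glucocorticoid-responsive genes and 1 immediate early gene had an unadjusted p under 0.05. DESeq2 called 1 glucocorticoid-responsive gene higher and 1 lower and 1 immediate early gene higher, and limma-voom called 0 in both lists. When WT_159 was left out edgeR called the glucocorticoid-responsive genes Pdk4 higher and Fbxo32 lower and the immediate early gene Cyr61 higher, and with any other library left out 0 in both lists.

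The integrated stress and unfolded protein response had 0 of 19 past the threshold (camera adjusted p = 0.984), with Xbp1 at a log2 fold change of 0.29 (adjusted p = 0.105) and Phgdh at -0.67 (adjusted p = 0.202). Its median of -0.01 and mean of -0.06 went against its upward test. Heat shock proteins had 0 of 17 (camera adjusted p = 0.868), with Dnaja1 at 0.31 (adjusted p = 0.187) and Dnajb4 at 0.25 (adjusted p = 0.350). The antioxidant response had 0 of 24 (camera adjusted p = 0.898, median 0.03 and mean -0.01), with Gclc at -0.31 (adjusted p = 0.178) and Gsta4 at 0.29 (adjusted p = 0.258). The interferon response had 0 of 21 (camera adjusted p = 0.775), with Iigp1 at 0.46 (adjusted p = 0.372) and Ifit3 at -0.25 (adjusted p = 0.493). Adjusted over each list alone, 1 immediate early gene and 1 gene of the integrated stress list rose, and the heat shock, antioxidant, interferon, glucocorticoid and calcium handling lists held 0 changed genes. At an unadjusted p under 0.05 edgeR had 4 genes of the integrated stress list, 2 heat shock, 3 antioxidant and 0 interferon genes. DESeq2 called 1 gene of the integrated stress list higher and 0 in the other 3 lists, and limma-voom called 0 in all of them. With WT_159 left out edgeR called 3 antioxidant genes, Gstm2 higher and Gclc and Nqo1 lower, and with any other library left out 0.

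White adipocyte markers had 0 of 18 past the threshold and a median log2 fold change of -0.93 (camera adjusted p = 0.00394, and an adjusted p of 0.807 with an estimated correlation), with Scd1 at -1.20 (adjusted p = 0.289) and Lep at -1.71 (adjusted p = 0.326). Their mean varied widely within the groups, from -0.95 in WT_160 to 0.74 in WT_159 and from -1.60 in ARKO_165 to 0.04 in ARKO_163. Markers of Schwann cells and nerve had 0 of 11 and a median of -0.52 (camera adjusted p = 0.000572, and an adjusted p of 0.699 with an estimated correlation), with Cadm4 at -0.53 (adjusted p = 0.177) and Prx at -0.56 (adjusted p = 0.187). Their mean was 0.50 in WT_159 and between -0.25 and -0.02 in the other controls, and ARKO_163 (-0.01) lay above these 3 controls. Markers of pericytes and smooth muscle had 0 of 12 and a median of -0.27 (camera adjusted p = 0.00248, and an adjusted p of 0.610 with an estimated correlation). Their contractile genes Myh11 and Tagln stood at -0.55 (adjusted p = 0.0596) and -0.43 (adjusted p = 0.112). The mean of the list in ARKO_163 (-0.06) was above that in the control WT_160 (-0.14). Adjusted over the list alone, 4 pericyte and smooth muscle markers and 3 Schwann cell markers fell, and 0 white adipocyte markers changed. Unadjusted, 2 white adipocyte, 6 Schwann cell and 6 pericyte and smooth muscle markers had a p under 0.05 in edgeR. DESeq2 called 0, 1 and 2 of them, all lower, and limma-voom called 0. In edgeR the Schwann cell marker Ngfr was called higher without WT_159 and Myh11 lower without ARKO_163.

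Extracellular matrix genes had 0 of 29 past the threshold and a median log2 fold change of 0.24 (camera adjusted p = 5.28e-05, and an adjusted p of 0.700 with an estimated correlation), with Ctgf at 0.56 (adjusted p = 0.1297) and Lox at 0.68 (adjusted p = 0.189). Their mean was 0.26 in WT_159 and 0.18 in WT_161, above ARKO_164 (-0.05). Tenocyte and myotendinous junction markers had 0 of 12 and a median of 0.35 (camera adjusted p = 0.000572, and an adjusted p of 0.661 with an estimated correlation), with Cilp2 at 0.71 (adjusted p = 0.157) and Tnmd at 0.63 (adjusted p = 0.185). Their mean in WT_161 (0.22) was above ARKO_164 (0.17). Fibro-adipogenic progenitor markers had 0 of 13 and a median of 0.19 (camera adjusted p = 0.0164, and an adjusted p of 0.699 with an estimated correlation), with Serpinf1 at 0.24 (adjusted p = 0.283) and Lum at 0.44 (adjusted p = 0.288). Their mean in WT_159 (0.17) was above ARKO_170 (0.14) and ARKO_164 (0.05). At an unadjusted p under 0.05 edgeR had 4 matrix, 4 tenocyte and 3 progenitor genes. DESeq2 called 2, 2 and 0 of them, all higher, and limma-voom called 0. Adjusted over the list alone, 0 genes of these lists changed. With WT_159 left out edgeR called the matrix genes Ctgf and Lum higher, Lum also as a progenitor marker, and with any other library left out 0.

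Endothelial (0 of 16, camera adjusted p = 0.582), macrophage (0 of 15, camera adjusted p = 0.119), brown adipocyte (0 of 8, camera adjusted p = 0.888), erythroid (0 of 7, camera adjusted p = 0.540) and lymphocyte and neutrophil markers (0 of 7, camera adjusted p = 0.861) were not past the threshold. Members of these lists with the smallest p were Kdr (-0.32), Mrc1 (0.56), Ppara (0.35), Bpgm (0.17) and Igkc (-3.84), none past the threshold. Igkc was highest in WT_158 (10.1 CPM) and WT_161 (3.74 CPM) and at most 0.293 CPM in the other libraries. At an unadjusted p under 0.05 edgeR had 1 endothelial, 0 macrophage, 1 brown adipocyte, 0 erythroid and 2 lymphocyte and neutrophil markers. DESeq2 and limma-voom called 0 in these 5 lists, and 0 changed adjusted over each list alone. Without WT_159 edgeR called 1 of them, the brown adipocyte marker Cpt1a, higher. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were expressed in all 8 libraries, with log2 fold changes of 0.45, 0.55, 0.49 and 0.21 and 0 past the threshold in edgeR, while Xist had at most 3 counts in a library. Of these 4 Y-linked genes 3 rose adjusted over the list alone and had an unadjusted p under 0.05 in edgeR, DESeq2 called 1 higher and limma-voom called 0. Without WT_159 edgeR called Uty higher.

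**Figure D3:**
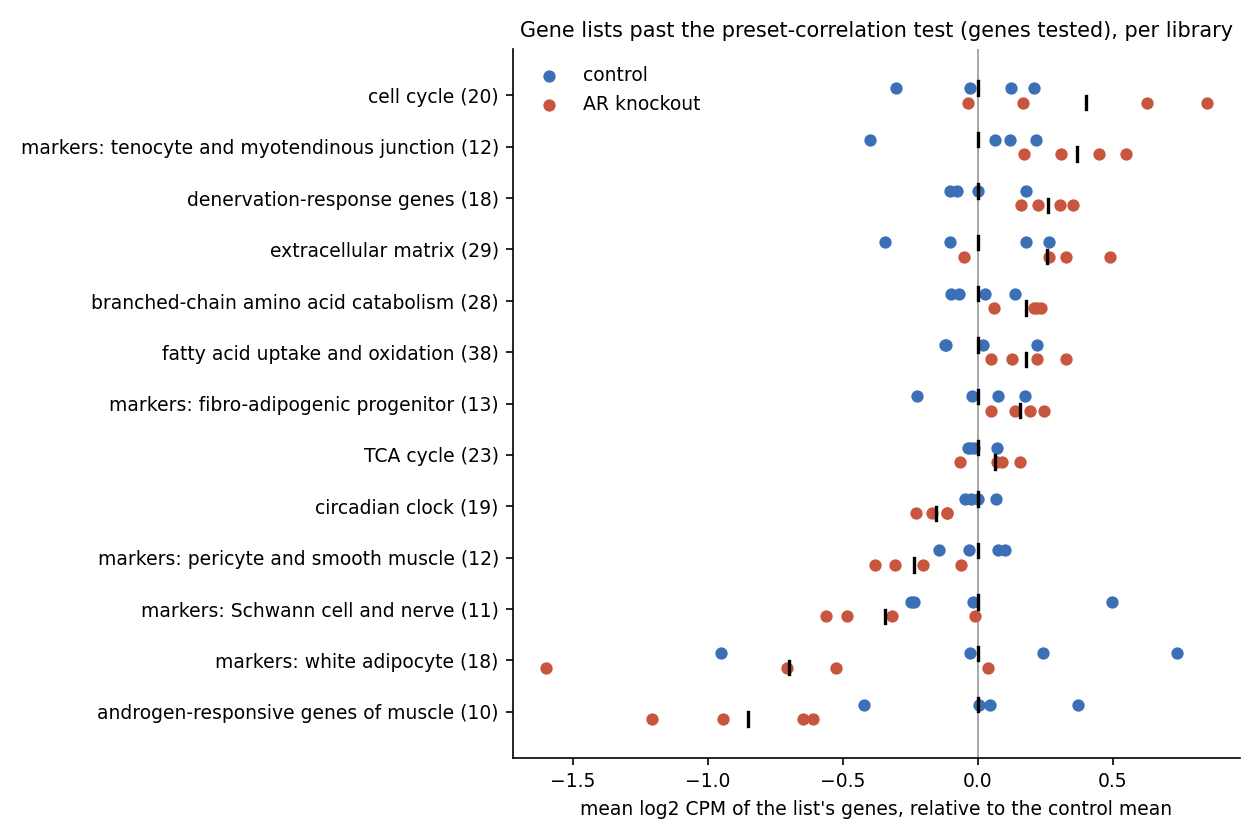
Mean log2 CPM of the genes in each of the 13 lists past the preset-correlation test, relative to the control mean, with a dot for each control and knockout library and a black tick for the group mean. The androgen-responsive genes lie at -1.21 to -0.61 in the knockout libraries, and for several lists, such as the white adipocyte markers, the dots of the 2 groups overlap.

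In all, 13 of the 34 tested lists were past the threshold with the preset correlation, 8 upward and 5 downward. None was past it with an estimated correlation between genes (0 of 34, smallest adjusted p 0.472), and fry found 0 lists that moved on balance in the same direction (smallest adjusted p 0.0999) and 9 that changed in either direction. The 9 were the androgen-responsive, polyamine, branched-chain, embryonic and regeneration, denervation, atrogene, growth-factor, pericyte and smooth muscle, and satellite cell lists. Unadjusted, 3 lists with an estimated correlation and 6 by fry in the same direction had a p under 0.05. Of the 35 splits of the 8 libraries into 4 and 4, the real split included, 13 gave at least 13 lists, so the number of lists is not larger than regrouping gives.

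The authors' deposited table held 497 genes that had an adjusted p under 0.05, 224 of them higher and 273 lower in the knockout. These calls come from the same libraries and are not independent, so the overlap is a description only. All 156 genes called here by edgeR were among the 497, with the same sign. Of the remaining 341 genes, 308 were tested here and 308 of these had the same sign, with a median adjusted p of 0.107. At an adjusted p under 0.01 the authors' deposited table held 265 genes, and 155 of the 156 were among them. For Ar the authors' deposited table gives a log2 fold change of -3.59.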

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

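The tests of WT_159 were chosen after its values had been seen, while the test for stray values within a group was fixed before the data were examined. That test marked 12 of 258 groups of values, where chance gives 12.9, so the number of marks is what chance gives.

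In the knockout group, Mss51 stood at 24.02 CPM in ARKO_170 against 13.0 to 14.6 CPM in the other libraries. Otop1 stood at 0.259 CPM in ARKO_170 against 0.194 to 0.204 CPM. Ifit3 stood at 1.58 CPM in ARKO_164, below the 2.05 to 2.10 CPM of the others. Myh2 stood at 2898 CPM in ARKO_164 against 2096 to 2138 CPM. Prx stood at 19.7 CPM in ARKO_163 against 13.1 to 13.4 CPM. The mean log2 CPM of branched-chain amino acid catabolism, relative to the control mean, was 0.0591 in ARKO_163 and 0.21 to 0.24 in the other knockout libraries.

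In the control group, Otog stood at 5.46 CPM in WT_161 against 1.80 to 2.31 CPM in the other libraries. Ndufab1 stood at 97.4 CPM in WT_160 against 86.8 to 87.8 CPM. Cd79b, a B cell gene, stood at 5.73 CPM in WT_158 against 0.256 to 0.559 CPM. Egfl7 stood at 27.3 CPM in WT_159, below the 35.6 to 36.5 CPM of the others, and Cadm4 at 7.89 CPM, above their 5.48 to 5.75 CPM. The mean log2 CPM of heat shock proteins was -0.10 in WT_159 and 0.02 to 0.04 in the other controls.

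On a scale from the other controls at 0 to the knockouts at 1, the control library WT_159 had a median position of 0.369 in the 156 changed genes and of 0.658 in the 533 scored genes called without it, while WT_158, WT_160 and WT_161 had -0.199, -0.0631 and -0.144 in the 156 genes and -0.0479, 0.163 and -0.0380 in the genes called without each. Knockout RNA mixed into WT_159 at the share those 533 genes give (67.6%) would leave an Ar level of 16.1 CPM, but the level was 51.0 CPM against 42.0 ± 4.54 (SD) in the other 3 controls, which speaks against a mixture. A single wrong scaling factor moves rising and falling genes the same way, yet both moved towards the knockout, with median positions of 0.679 for genes that rose and 0.631 for genes that fell among the 533. Lower androgen signalling in that mouse may also place it there. On the knockout side lay 7 of 7 androgen-responsive genes not called and 73.4% of 14443 other uncalled genes (exact binomial p = 0.115, one-sided). This is the smallest p that 7 genes can give at that share, so the test could not decide. Genes of the androgen list also varied together (estimated correlation 0.261), which the binomial test ignores. Hormone levels were not given, so lower androgen signalling stays open as an explanation, as do other differences between mice, which were not tested.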

How the results depend on the processing

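The fits with sample quality weights, without Gm42418 and AY036118, and without WT_159 and ARKO_163 together were chosen after the data had been seen. The 156 genes changed (57 higher, 99 lower) became 102 (31 higher, 71 lower) with library size alone. They became 501 (225 and 276) with DESeq2, which was run without filterByExpr, and 301 (136 and 165) in edgeR with no filter. DESeq2 on the filtered genes was not run. The count was 56 (15 and 41) with a 2-fold minimum, 279 (126 and 153) with quality weights and 411 (182 and 229) without WT_159 and ARKO_163. With 1 library left out the count ran from 16 (without ARKO_165) to 550 (without WT_159), from 4 to 246 for higher genes and from 11 to 304 for lower genes. The cause was not tested. DESeq2 size factors (152), upper-quartile factors (151), limma-voom (124) and the 1 CPM filter (138) stayed within 1.5 times of the main count. So did leaving out Gm42418 and AY036118 with TMM (159) or with library size alone (114). Ar kept its direction and its call in every fit listed here. The 13 gene lists became 0 with an estimated correlation and 0 by fry. They were also 0 without WT_159 and ARKO_163 with an estimated correlation, and the cause was not tested. Their estimated correlations ran from 0.00991 (circadian clock), not above the preset 0.01, to 0.756 (Schwann cell and nerve markers). The circadian list still went from a camera adjusted p of 0.0303 to 0.490. A higher correlation of its own genes does not account for that loss. The number of lists was 12 with library size alone, 11 without WT_159 and ARKO_163, and from 10 to 14 with 1 library left out. Among 90 named genes 0 turned direction while called. For the main calls this was nearly fixed when 1 library was left out, since their groups did not overlap. With library size alone 7 named calls were lost, with limma-voom 6 and with no filter 6, while DESeq2, run without filterByExpr, added 13. No paired analysis was possible because the column names of the counts match no replicate number in the sample titles, so the planned replicate block was not run. The planned pseudocounts were not run because the table holds raw counts. With 4 libraries in each group, simulated genes changed 1.5-fold were recovered in 50.2% of cases by edgeR, so changes of this size can be missed.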

Other observations

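The genes in this paragraph and the tests of neighbouring genes were chosen after their values had been seen, while the regrouping of the libraries was planned. Nmrk2, a kinase that phosphorylates nicotinamide riboside to a precursor of NAD, fell 3.26-fold from 257 ± 56.5 to 78.9 ± 24.2 CPM (SD, n = 4 each). Npc1, which moves cholesterol out of lysosomes, fell 2.13-fold from 86.5 to 40.6 CPM, and Ldlr, the receptor for low-density lipoprotein, fell 1.71-fold from 12.0 to 7.002 CPM. Aldh1a1, a retinaldehyde dehydrogenase, fell 2.20-fold from 72.3 to 32.9 CPM. Gdnf, a neurotrophic factor, fell 3.48-fold from 0.600 to 0.176 CPM. Ccng1, a cyclin gene, rose 1.41-fold from 848 ± 88.9 to 1199.8 ± 86.5 CPM, and Car2, a carbonic anhydrase, rose 1.80-fold from 6.14 to 11.1 CPM. Among the 156 changed genes, 12 were called again in all 8 fits with 1 library left out, Car2 among them. Nmrk2, Npc1, Ldlr, Aldh1a1, Gdnf and Ccng1 were not among the 12.

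Of 231 tested solute carrier genes 6 fell and 0 rose, where 1.57 would fall if the 99 lower genes were spread evenly. Besides Slc30a2, Slc2a3 and Slc38a4 they were Slc16a3, a lactate carrier (log2 fold change -0.68), Slc16a9 (-0.73) and Slc40a1, the iron exporter (-0.92). A test of this family was made and left out, because the family was picked after its members had been seen.

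The number of changed genes was compared with that of other splits of the same 8 libraries into 4 and 4. Of 35 splits 1, the real one, gave 156 genes or more, and the highest of the others gave 14. The gene count is thus larger than regrouping of these libraries gives, but 35 splits are too few to exclude chance. The other splits place knockout libraries in both groups, so real differences widen their spread and lower their counts. For the gene lists 13 of 35 splits gave 13 lists or more, and the highest of the others gave 18, so chance cannot be excluded for the number of lists.

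Genes that fell lay beside each other more often than random sets matched on expression, with 5 pairs within 100 kb against a mean of 1.40 in 10000 random sets (permutation p = 0.0154), a test made after the pairs had been noticed in the same genes. At 50 kb there were 5 pairs against 0.839 (permutation p = 0.0022), and at 250 kb 8 pairs against 2.83 (permutation p = 0.0123). Genes that rose formed 0 pairs within 100 kb against a mean of 0.441 in random sets, too few to set them apart from genes that fell. Without WT_159, among 287 genes that fell, there were 33 pairs against 12.1 (permutation p = 0.0001, the smallest the draws can give), and among genes that rose 11 against 8.395 (permutation p = 0.223), but these sets include the genes above and are not independent of them. Transcription that runs on from a gene into the next is argued against in both pairs on opposite strands, Amd1 with Cdk19 and Ush1c with Otog, since 2 of these 2 pairs point away from each other, while without WT_159 the 33 pairs were 11 pointing away, 4 pointing towards each other and 18 on the same strand, so this holds for those 2 pairs and not for the larger set. It may account for the pairs on the same strand (Spns2 with Smtnl2, Mss51 with Anxa7, Gm15879 with Slx4), where in 3 of 3 the upstream gene fell by more, but 3 pairs are too few to decide, without WT_159 it was 10 of 18 pairs, and shared regulation was not tested.

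The ribosomal RNA-like transcript Gm42418 stood at 67299 CPM in ARKO_163 and between 2937 and 16249 CPM in the other libraries. In WT_158 the B cell genes Cd79a and Cd19 had 325 and 273 counts, while the other libraries had at most 17 and 26. Actc1, the cardiac actin gene, stood at 1689.9 CPM in WT_159, between 206 and 318 CPM in the other controls and between 1456 and 2814 CPM in the knockout libraries (log2 fold change 1.76, adjusted p = 0.389).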
